A study of Mus musculus with 4 samples.

How the data were processed

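Genomic DNA from liver was cut with TaqI and MspI, made into reduced representation libraries, bisulfite converted and amplified, per the labels' protocols. Each of the 4 libraries had a track of methylation levels and a track of read depth deposited by the authors, on build mm10 per the file headers. The headers name the program GBSA. The submitters' processing notes also name BWA 0.7.12 and MACS, without a role, and further steps are not given in the sources used here. In the deposited tracks a level is a fraction with a minus sign at reverse-strand cytosines, and the depth carries the same sign. Level times depth was a whole number at 100% of positions (tolerance 1e-06), which gave methylated and total reads.

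Both strands of a CpG were summed. Of 3485636 CpGs listed in any library, 2730561 were listed in all 4. Each library listed 3065573 to 3191412 CpGs, with a median of 13 or 14 reads over its own. CpGs with at least 10 reads in every library were analysed; at 10 reads with 5 methylated the 95% exact Clopper-Pearson interval runs from 18.7% to 81.3%, and a count of 0 allows up to 30%. Such intervals cover counting error only, since reads were amplified. Reads were also summed over 1-kb tiles and over windows around genes, each with at least 3 analysed CpGs.

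The gene annotation used here gives gene starts and ends on the same build but no strand, transcripts or sequence, so promoters, exons, CpG islands and repeats were not analysed here. In place of a promoter, the window of 1 kb on either side of the gene end with more listed CpGs was used, for 20753 protein-coding and lncRNA genes; 69.1% of these windows were below 20% methylation, against 20.6% at the other end. The end was picked by CpG number, so these shares do not show that a given window lies at a gene start. In place of annotated features, CpGs were classed by listed CpGs within 250 bp and by distance to genes. All 269 list genes were found in it.

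Each feature was tested with a moderated quasi-binomial model of methylated and unmethylated reads, with the Pearson dispersion shrunk by the method of limma 3.58.1 and held at 1 or above, a two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment. This is what "adjusted p" means for CpGs, tiles and gene windows. A call needed adjusted p under 0.05 and a difference of at least 10 percentage points; features with no or only methylated reads were not tested. Gene lists were tested with camera (preset correlation 0.01, and an estimated one) and fry in limma, on log2 ratios of methylated to unmethylated reads with 1 added to each. Genome-wide levels were compared with exact permutation tests. R 4.3.3, version 1.17.8 of the data.table package, pandas 2.3.3 and matplotlib 3.10.9 were used.

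The model was tested on simulated reads with the real depths and mean levels, 200 features of 35% to 65% mean level being changed by 10, 20 or 30 points. For tiles it recovered 2.99%, 52.2% and 83.3% of these, and for gene windows 8.96%, 59.7% and 90.9%; for CpGs it recovered 0% at 10 and 20 points and 4.55% at 30. Of the calls in simulated tiles, 20.7% were unchanged features, more than the 5% aimed at, and 7.02% for gene windows. The prior for the spread drew on all features, including those near full or no methylation, where the dispersion of a single feature is poorly determined. A prior estimated only on features with a binomial variance of at least 5 reads in each library lowered these shares to 12.7% and 2.94%. It was chosen on simulated data after the counts of the written model had been seen, and is called the other prior. The written model stayed the main one, since its design was set before the data were examined, as were the gene lists, the rule for named genes and most alternatives.

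By that rule the text names the called gene windows, up to 10 in each direction, Pnpla7, the called members of each list with up to 4 members by smallest p, and the 5 called CpGs and tiles with the largest difference each way and at least 20 reads per library. The number of members named per list was set at 2 or fewer, beyond those called, after values were seen. Alternatives covered coverage minimums, the size of difference, other tests, window shape, sex chromosomes, deep CpGs, the replicate numbers as a block and each library left out. A called tile of the fixed lists is not reported here.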

Results

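DNA methylation was measured by reduced representation bisulfite sequencing in the liver of 6-week-old C57BL6/N mice, with 2 libraries from Pnpla7+/+ animals (WT) and 2 from Pnpla7-/- animals (KO). Pnpla7 encodes a lysophospholipase that releases glycerophosphocholine from lysophosphatidylcholine, and the comparison asks how liver methylation differs without it. The files held 50413170 and 59437109 reads over cytosines in WT replicates 1 and 2, and 59953688 and 60535892 in KO replicates 1 and 2. At 1600691 nuclear CpGs each library had at least 10 reads, with medians of 21, 25, 25 and 25 reads in the same order. Across these CpGs the Pearson correlation was 0.975 between the WT libraries, 0.977 between the KO libraries, and from 0.975 to 0.976 between genotypes; CpGs are not independent replicates. The labels do not say whether the libraries of a genotype came from separate animals, so p-values measure at most the spread between these libraries. At single CpGs the main model gave every CpG the same dispersion, 1.09. Their p-values therefore reflect read counts and not the spread between libraries at that CpG.

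Pnpla7 itself lies on chromosome 2 from 24975990 to 25054072 (mm10), and 113 CpGs in it were listed. The window around its CpG-richer annotated end was almost unmethylated in both genotypes, at 0.586% ± 0.0762 (SD, n = 2) in WT and 0.61% ± 0.0667 in KO. A 1-kb tile inside the gene, from 25052001 to 25053000, rose from 31% ± 6.45 in WT to 56.3% ± 9.26 in KO (n = 2 each; 140 to 217 reads per library; adjusted p = 0.00663, moderated quasi-binomial model). It was 1 of 13 tiles tested in the gene. No CpG of Pnpla7 had at least 10 reads summed over the WT libraries and 0 in the KO libraries. The longest distance between neighbouring CpGs with at least 10 summed KO reads was 9173 bp. The covered CpGs therefore do not check the genotype labels. Within 5 Mb of Pnpla7, 5 of 1008 tested tiles were called, or 0.496%, against 0.0877% on the rest of the chromosome and 0.147% in the rest of the genome (Fisher's exact test, adjusted p = 0.00703 and 0.0377). Of single CpGs in that span 2 of 8079 were called, or 0.0248%, against 0.0136% and 0.0404% (adjusted p = 0.331 and 0.778). Within 10 Mb, 8 of 2211 tiles were called, 0.362% against 0.0686% and 0.146% (adjusted p = 0.00392 and 0.0377), and 9 of 17409 CpGs, 0.0517% against 0.00635% and 0.0401% (adjusted p = 0.000689 and 0.589).

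CpGs in sparse surroundings were more methylated in KO and those in dense surroundings less, with larger differences at intermediate mean levels than over each whole class. Among CpGs of intermediate mean level (20% to 80%), those with 1 to 4 listed CpGs within 250 bp on either side averaged 60.6% ± 0.46 in WT and 62.9% ± 0.474 in KO (SD, n = 2). CpGs with 20 or more neighbours in that span, as is common at gene starts, averaged 42.8% ± 0.956 in WT and 39.8% ± 0.664 in KO, a difference of -3.02 percentage points. These were 16012 of 588560 dense CpGs. Over all dense CpGs the mean was 3.85% ± 0.0262 in WT and 3.7% ± 0.0644 in KO, a difference of -0.151 points. Over all sparse CpGs it was 77.2% ± 0.263 and 78.2% ± 0.325. The 9712 dense CpGs on the X chromosome, a part of the dense class, averaged 21.4% ± 0.26 in WT and 19.4% ± 0.156 in KO. The whole X chromosome averaged 57% ± 0.146 and 56.9% ± 0.568, with the KO libraries on either side of the WT libraries. Over all 1600691 CpGs the mean level was 44.8% ± 0.151 in WT and 45.2% ± 0.0363 in KO, and 409 of 445 windows of 5 Mb were higher in KO. In each of these classes other than the whole X chromosome, both KO libraries lay on the same side of both WT libraries. This gives an exact permutation p of 0.333 (two-sided), the smallest that 2 libraries against 2 allow. Weighting CpGs by reads turned the global difference from 0.337 to -0.725 percentage points. The libraries then overlapped, at 40.3% and 38.7% in WT replicates 1 and 2 and 37.9% and 39.7% in KO replicates 1 and 2.

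**Figure D1:**
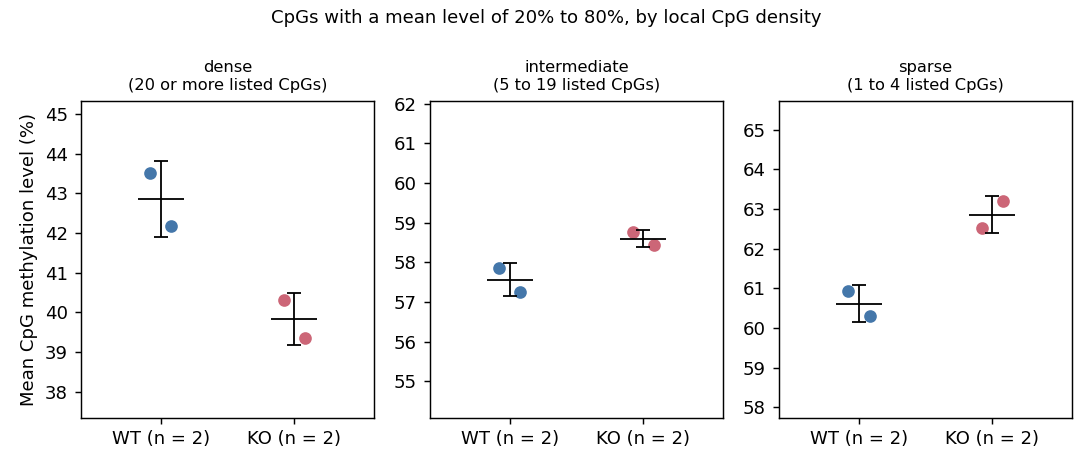
Mean CpG methylation level (%, vertical axis, not starting at 0) in WT and KO liver for CpGs with a mean level of 20% to 80%, in 3 classes of local CpG density. Points are libraries and bars the mean ± SD (n = 2); KO means are 39.8% against 42.8% at dense CpGs and 62.9% against 60.6% at sparse CpGs.

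Of 11 called tiles of 1 kb in or within 10 kb of a gene of the fixed lists, 9 were higher in KO and 2 lower. A tile in Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose from 69.8% ± 8.72 to 85.4% ± 0.469 (SD, n = 2 each), and one in Foxa1, a pioneer transcription factor of hepatocytes, from 6.57% ± 0.597 to 17.3% ± 1.21. A tile within 10 kb of Srebf1, a regulator of lipid synthesis, lies in Rai1 and rose from 42.2% ± 5.01 to 71.6% ± 8.61. A tile in Akap5, within 10 kb of the folate enzyme gene Mthfd1, fell from 56.4% ± 2.43 to 41% ± 4.12. Adjusted p from the moderated quasi-binomial model was 0.000222 for Cyp7a1, 4.27e-07 for Foxa1, 0.000182 for the Rai1 tile and 0.00108 for the Akap5 tile.

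Of 163610 tiles tested, 244 were called, 176 higher and 68 lower in KO, with median differences of 20.3 and -14.7 percentage points. Annotated genes held 185 of them, and 55 more lay within 50 kb of a gene end. Tiles with 20 or fewer listed CpGs gave 160 higher and 35 lower calls, and tiles with more gave 16 higher and 33 lower (Fisher's exact test, p = 6.91e-11). Fisher's exact tests on numbers of called tiles or CpGs take these as units. Their p does not measure the spread between libraries. The largest rises with at least 20 reads in every library were near Mroh4 (27.6% ± 0.62 to 84% ± 1.52; SD, n = 2 each), Card10 (26.7% ± 4.64 to 76.3% ± 28.7), Kcnk16 (27.6% ± 4.19 to 64.8% ± 1.71) and Gm34201 (52.8% to 89.2%) and, with no gene within 50 kb, on chromosome 15 from 74128001 to 74129000 (49.2% to 85.6%). All but the Kcnk16 tile lie in the chromosome 15 segment described separately here. The Mroh4 tile rests on 3 CpGs, 1 of them (74638824) at 0% in both WT libraries and 87.2% and 77.4% in KO. The tile without a gene also held such a CpG (74128295), and 7 of the 244 tiles held a CpG at or below 10% in some libraries and at or above 70% in the rest. The largest falls were near Ptp4a2 (83.2% to 48.6%), in Med12l and P2ry12 (48.6% to 17.1%), in E030011O05Rik (87.1% to 60.0%), near Rgs16 (52.2% to 26.1%) and near Tubg1 (48.5% to 22.5%). The other 2 splits of the 4 libraries called 21 and 30 tiles. A prior for the spread that was chosen after a simulated check, described with the processing, left 129 calls, 100 higher and 29 lower, against 7 and 11 in those splits. It did not call the Card10, Med12l, E030011O05Rik and Rgs16 tiles, and the E030011O05Rik call was lost whichever library was left out. The excess of higher calls was lost without KO replicate 1, at 98 higher and 103 lower, and smaller without WT replicate 2, at 79 and 64, with 114 and 89 of the 244 among them. Whichever library was left out, 47 of the 244 tiles were called.

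In the fatty acid oxidation list, a tile was called in Ppara, a nuclear receptor that regulates this pathway (28.8% ± 0.702 to 51.8% ± 3.01; SD, n = 2 each). This call was lost with the other prior, at adjusted p = 0.0801 in the moderated quasi-binomial model. In the growth hormone and stress list, 2 of 182 tiles were called. One is in Mief1, within 10 kb of Atf4 (53.5% ± 3.08 to 87.1% ± 2.07), and the other in Igfals (64.8% ± 10.6 to 76.6% ± 2.73), which the other prior did not call. In the phospholipid list, a tile in Mcoln1 near Pnpla6 rose from 39.5% to 54.9%, and one in Cpt1b near Chkb fell from 74.2% to 63.3%; the other prior called neither. The Ppara and Mief1 tiles lie in that chromosome 15 segment. Of tested tiles, 1.12% were called in the fatty acid oxidation list and 1.1% in the growth hormone and stress list, against 0.148% elsewhere for each, and no list passed the adjusted threshold for an excess (Fisher's exact test, lowest adjusted p = 0.153 over 15 lists).

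**Figure D2:**
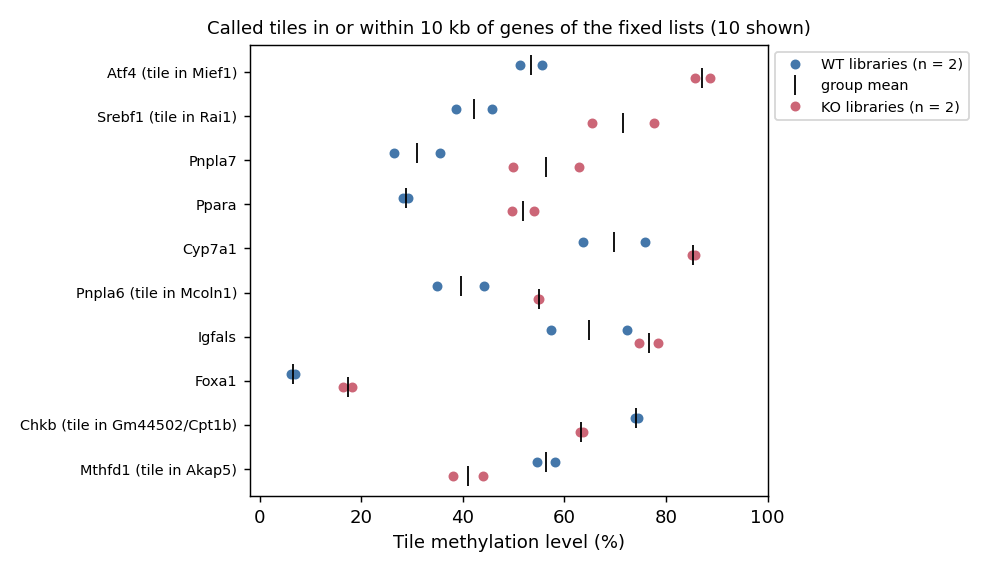
Methylation level (%, horizontal axis) of 10 of the 11 called tiles in or within 10 kb of a gene of the fixed lists. Points are libraries (n = 2 per genotype) and ticks the group means; the Foxa1 tile goes from 6.57% in WT to 17.3% in KO, and the Akap5 tile near Mthfd1 from 56.4% to 41%.

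At annotated gene ends, picked by CpG number in place of promoters, 16 of 20689 windows passed the test, 7 higher and 9 lower in KO. Without strand, a window may lie at the start or the end of its gene. Of the called windows only that of Bik had a WT mean below 20%. Hamp, the gene of the iron hormone hepcidin, measured 65.4% ± 1.06 in WT and 87.4% ± 2.83 in KO (SD, n = 2), and Srebf1 47.1% ± 2.34 and 62% ± 5.99. The other higher windows belonged to Defb14, Apobec3, Gm41851, Odf3l1 and Serpinf2. Bik, a BH3-only apoptosis gene, measured 15.4% ± 0.541 in WT and 5.03% ± 2.79 in KO, and Abi3 41.7% ± 8.03 and 24.5% ± 7.51. The other lower windows belonged to Ndufc2, Gm16063, Akap5, Pnma1, Polrmt, Vmn2r29 and B3galt4. Adjusted p was 0.011 for Hamp, 0.0463 for Srebf1, 1.99e-05 for Bik and 0.00862 for Abi3 in the moderated quasi-binomial model. The other 2 splits called 2 and 7 windows; with the other prior 4 were called, Bik, Vmn2r29, Polrmt and B3galt4, against 2 and 4 in those splits. The count was 4 without WT replicate 1, 10 without WT replicate 2, 18 without KO replicate 1 and 30 without KO replicate 2, of which 1, 1, 5 and 14 were higher in KO and 1, 5, 5 and 12 were among the 16, and no window was called whichever library was left out.

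Among the fixed lists, Srebf1 was the 1 gene end called over all windows. Its window overlaps the Rai1 tile, and the Akap5 and Igfals windows overlap the tiles named for those genes. Such windows and tiles are not independent findings. Adjusted over the list alone, the count was 1 in the growth hormone and stress list (Igfals, 63.4% to 74.7%), 2 in the hepatocyte list (Tat, 44.9% to 64.1%, and Cyp2e1, 47.2% to 30.1%), 1 in the lipid synthesis list (Srebf1) and 2 in the imprinted list, Peg10 and Sgce, which share a window (37.7% to 26.5%). In the imprinted list 16 of 23 windows were lower in KO, with a median difference of -2.68 points. At a mean level of 20% to 80%, 12 of 17 imprinted windows were lower, with a median of -3.48 points, and so were 187 of 266 other windows with 40 or more listed CpGs, with a median of -2.05 points. The immune marker list had 6 of 8 windows lower and a median of -3.68 points, and the hepatocyte list 9 of 13 higher and a median of 0.526 points. The methyl donor list had 16 of 30 windows higher, the DNA methylation machinery list 8 of 14, and the germline list 12 of 18 lower, at levels of 79.7% in WT and 78.2% in KO. In the phospholipid list 20 of 27 were higher, in the lipid synthesis list 18 of 27, and in the fatty acid oxidation list 6 of 15. The fetal liver list had 7 of 8 lower, the cholangiocyte list 5 of 6, the stellate and fibroblast list 4 of 7 and the endothelial list 2 of 3. Median differences were 0.0153 points in the methyl donor list, 0.0631 in the machinery list and -1.02 in the germline list. They were 0.192 in the phospholipid list, 0.214 in the lipid synthesis list and -0.183 in the fatty acid oxidation list. In the fetal liver, cholangiocyte, stellate and endothelial lists they were -0.217, -1.78, -0.037 and -0.241. No list passed camera (limma), with adjusted p of 0.35 or above at the preset correlation and 0.87 or above with an estimated correlation. In fry's mixed test, of change in either direction, the DNA methylation machinery list had adjusted p = 0.00573 and the growth hormone and stress list 0.0214 (limma). In fry's directional test both had adjusted p = 0.844, and the lowest over the lists was 0.684 (limma); the machinery list had no called gene end and no called tile among 197.

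Of single CpGs, 509 of 1263975 tested were called, 406 higher and 103 lower in KO. The highest rises were on chromosome 15, in Ptp4a3 at 73739647 (0% to 95.2% ± 1.76; SD, n = 2) and 73758464 (1.35% to 91.7%), in Dennd3 at 73518910 (0% to 93.3%), in Slc45a4 at 73586292 (0% to 89.7%) and near Ptp4a3 at 73767204 (0% to 88.4%). The largest falls were in Bik at 83527319 (67.9% ± 4.12 to 8.97% ± 12.7), near Gm12169, in Nf2, in Lynx1 and in Ccdc69. The Gm12169 CpG measured 100%, 84.6% and 77.3% in WT replicates 1 and 2 and KO replicate 1, and 0% in KO replicate 2. Without KO replicate 2 the Ccdc69 difference of -46.7 points was 0.85, and neither of these CpGs was called. The Nf2 and Lynx1 CpGs were called in none of the runs that left out 1 library. The other 2 splits called 335 and 324 CpGs. With the other prior 98 CpGs were called, 94 of them higher, against 0 and 15. Each run that left out 1 library estimated the spread between libraries anew. A call lost in such a run can therefore come from the changed estimate as well as from the library. Without WT replicates 1 and 2 the Ccdc69 difference stayed at -46.6 and -46.7 points, yet its call was lost. Without WT replicates 1 and 2 and KO replicates 1 and 2 in turn, the count was 180, 140, 127 and 143, with 121, 119, 96 and 127 of the 509 among them. Of these calls 169, 138, 68 and 126 were higher and 11, 2, 59 and 17 lower, so the excess of higher calls was mostly lost without KO replicate 1.

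Chromosome 15 held 33 called tiles of 7091 tested, 0.465% against 0.135% elsewhere (Fisher's exact test, adjusted p = 1.84e-07). At 36 CpGs with at least 5 reads in every library, both WT libraries were at or below 10% and both KO libraries at or above 70%, and 34 of them lay on chromosome 15 between 73474421 and 86723329. Of these 34, 26 lay between 73474421 and 74819031, and the rest were spread out from 78280898 on. No CpG among the 2352469 examined showed the opposite pattern. CpGs within 200 bp of the 34 differed by a median of 1.52 points (quartiles -5.47 and 6.54, 123 CpGs). The segment held 26 called tiles, 22 higher and 4 lower, among 2255 tested. It includes the gene ends of Apobec3 and Bik, both in the part beyond 78280898 where such CpGs were few.

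**Figure D3:**
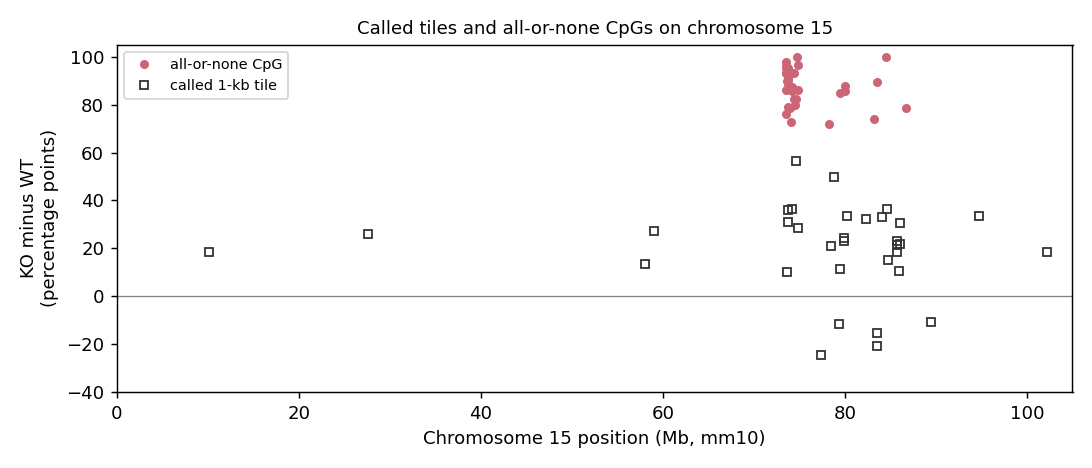
KO minus WT difference (percentage points, vertical axis) along chromosome 15 (Mb, mm10) for called 1-kb tiles (squares) and for CpGs at or below 10% in both WT and at or above 70% in both KO libraries (circles). The 34 circles lie between 73474421 and 86723329, with 26 of the 33 squares. Of the circles, 26 lie between 73474421 and 74819031.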

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

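All tests in this part were chosen after the results they bear on were seen. Mitochondrial cytosines entered none of the tests of CpGs, tiles and gene windows. Their methylated reads made up 0.395% in WT replicate 1, 0.442% in WT replicate 2, 0.432% in KO replicate 1 and 0.407% in KO replicate 2. The limits that a count of 0 allows were 0.00149%, 0.00117%, 0.00124% and 0.00115%. With 793 or more methylated reads per library, exceeding such limits was certain. These levels serve below as a check of conversion.

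The CpGs of chromosome 15 that were unmethylated in both WT libraries and methylated in both KO libraries may reflect a sequence difference. A cytosine replaced by thymine reads as unmethylated, and CpGs within 200 bp kept their level, with a median difference of 1.52 points (quartiles -5.47 and 6.54). A methylation change at most CpGs of the segment is argued against by its other 31337 CpGs, whose median difference was 0 points and mean 0.419. Genome-wide, 720162 of 1600691 CpGs averaged below 20% and 583156 above 80%. A median can therefore miss a change confined to CpGs of intermediate level, and the segment held 22 higher and 4 lower called tiles. The segment lies on another chromosome than Pnpla7, and which allele the reads carried was not tested. Methylation differences linked to such a segment stay open for the Ppara, Mief1 and Bik tiles in it. These lie beyond 78280898, where such CpGs were few, and whether the segment is continuous was not tested.

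The 244 called tiles were weighed against 3 explanations. Of the 3 splits of the 4 libraries, 1, the real one, gave as many tiles and the highest other gave 30, but 3 splits are too few for a share under 0.05. Single CpGs as the whole cause are argued against by 138 tiles called without the CpG that differed most. With the other prior 129 tiles were called, against 7 and 11 in the other splits. That prior comes from the same libraries, and its simulated check drew the spread from the main fit. Too small an estimate of the spread therefore stays open. Part of the calls may still rest on single CpGs, and all or part on too small an estimate of the spread. A difference between genotypes and a difference between 2 pairs of animals, litters or library batches were not separated by this design.

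Dense CpGs were lower and sparse CpGs higher in KO. Incomplete conversion is argued against by the mitochondrial level, whose mean differed between genotypes by 0.00128 points. A bias of amplification or alignment by CpG density could lower imprinted windows, where parental alleles hold the level near the middle; their median difference was -3.48 points, beside -2.05 in other CpG-rich windows of that level, but the quartiles of -5.10 and 1.09 leave this open. A different share of immune cells could also contribute: immune marker windows had a median of -3.68 points (quartiles -4.60 and -0.526), while the quartiles of hepatocyte marker windows, -0.312 and 2.33, span 0, so this cannot be told apart from a change within hepatocytes. The genotype stays among the open explanations.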

How the results depend on the processing

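Alternatives with the other prior, without the chromosome 15 segment, without all-or-none CpGs, without the most different CpG of a tile and with the other gene end were chosen after the data were seen; the cause of a change was not tested unless stated. The negative binomial alternative had been planned only for files deposited as counts and was not run.

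The global difference kept its direction (0.171 to 0.473 points) except when weighted by reads (-0.725); leaving out 1 library gave 0.23 to 0.443. At a minimum of 20 reads the density classes kept theirs; at a mean level of 20% to 80% the differences were 1.72 points at sparse, 0.812 at intermediate and -3.04 at dense CpGs, and -2.16 at dense CpGs of the X chromosome. No gene list passed camera under either alternative.

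Tile calls numbered 369 at a minimum of 5 reads, 56 at a difference of at least 25 points, 1109 with Fisher's exact test on pooled reads, which ignores the spread between libraries, 0 with limma on log ratios (which recovered 0 of 67, 67 and 66 simulated tiles changed by 10, 20 and 30 points), 113 with at least 5 covered CpGs, where fewer tiles are tested, 138 without the most different CpG and 129 with the other prior. Gene-end calls numbered 9 at a minimum of 5 reads, 30 at 20 reads, 1 at 25 points, 29 with no minimum difference, 132 with Fisher's exact test, 0 with limma, 4 with the other prior and 6 at the other gene end. CpG calls numbered 192 with limma and 98 with the other prior. At an unadjusted p under 0.05 limma gave 9035 of 163610 tiles and 1133 of 20689 gene ends, and the main model 10527 and 1360. In the simulated data, limma gave such a p at 5.17% of unchanged tiles and 5.67% of unchanged gene ends. The main model gave it at 5.46% and 5.58%. These counts are therefore not read as changes.

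Leaving out 1 library gave 143 to 267 tile calls, 4 to 30 gene-end calls and 127 to 180 CpG calls; the lone library of a genotype was then assumed to vary like the pair. With the replicate number as a block, calls went to 405 tiles, 40 gene ends and 357 CpGs. The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.00844 across tiles.

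Among named features, values changed sign for Pnpla7 (-0.33 points at a minimum of 20 reads, -0.22 with windows from 2 kb outward to 500 bp inward; -0.0296 to 0.0781 without 1 library), Kdr (0.499 at 5 and 0.0455 at 20 reads; -0.559 to 0.0764 without 1 library), Ahcy (1.13) and Col1a2 (1.57) with those windows, and Abi3 (2.88), Gpc3 (4.35; -5.38 to 0.646 without 1 library) and Coro1a (1.49) at the other gene end. The Ccdc69 CpG went from -94.2 to 0.85 points without 1 library. At the depth of single CpGs, 4.55% of simulated changes of 30 points were recovered.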

Other observations

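The runs that left out each library in turn had been planned. The other tests in this part were chosen after values were seen. Of the 244 called tiles, 47 were called whichever library was left out, 33 higher and 14 lower in KO, and the other prior called all 47. Several lie in genes outside the fixed lists. A tile in Alas1, the rate-limiting enzyme of heme synthesis in liver, rose from 30.4% ± 5.14 to 58.5% ± 0.418 (SD, n = 2 each). Tiles also rose in Fads1, a fatty acid desaturase (30.6% to 55.8%), in the estrogen receptor gene Esr1 (32.4% to 55.4%), in the prolactin receptor gene Prlr (17.4% to 35.8%), in the cell cycle gene Ccnd1 (39.4% to 66.7%) and in Zbtb20, a repressor of Afp in liver (57.2% to 76.0%). Tiles fell in Espn (59.2% to 37.7%), Hapln4 (29.3% to 12.2%) and Gli1, a transcription factor of hedgehog signalling (39.1% to 24.5%).

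Genes of the nuclear factor I family, transcription factors that bind as dimers, were called in both directions. A tile in Nfib rose from 35.7% ± 0.431 to 57.6% ± 1.69 (SD, n = 2 each), one in Nfic from 28.4% ± 6.92 to 48.9% ± 1.14 and one near Nfic from 14.8% ± 1.6 to 31.8% ± 5.74. Adjacent tiles in Nfix on chromosome 8 fell, from 47.1% ± 1.59 to 33.4% ± 0.795 and from 62.9% ± 0.86 to 51.6% ± 0.18. The family was singled out after its values were seen and was not tested for enrichment.

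All-or-none CpGs also marked single libraries: 37 CpGs were at or below 10% in WT replicate 2 and at or above 70% in the others, 23 of them on chromosome 3, and 16 in KO replicate 2, 8 of them on chromosome 11 between 46508904 and 55062306. The corresponding counts were 19 for WT replicate 1 and 8 for KO replicate 1. In the opposite pattern, high in 1 library and low in the others, 32 CpGs marked KO replicate 1. Of these, 26 lay on chromosome 3 between 95167542 and 104774636. The counts were 3, 3 and 2 for WT replicate 1, WT replicate 2 and KO replicate 2. The chromosome 11 CpGs of KO replicate 2 include those near Gm12169 and in Ccdc69. Clusters of CpGs at opposite levels in 2 libraries of 1 genotype argue against both libraries coming from the same animal. The underlying sequence was not tested.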
